A study of Mus musculus with 9 samples.

How the data were processed

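RNA of intestinal epithelial cells from newborn mouse pups (postnatal day 0) was measured on 9 Affymetrix Mouse Genome arrays, 3 for each of 3 genotypes. Control pups carried floxed Tfr1 alleles. Knockout pups were the intestinal epithelial knockout of Tfr1. Rescue pups carried the same knockout and, in addition, a Tfr1 allele with the R654A change at the ROSA26 locus. Per the labels, pieces of small intestine and proximal colon were kept for 30 min in 2 mM EDTA and shaken, and the released cells passed a 70 µm mesh. The labels name no sort by a surface marker, do not give the sex of the pups, and do not state whether an array holds RNA of 1 pup or of several. The p-values therefore measure the spread between arrays and nothing beyond it.

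The deposited values are log2 RMA values, 1 per probe set and array, as the authors' processing notes name RMA and Partek 6.5. The part each tool played, the background step and any probe filter are not given in the sources used here. The 9 columns hold 45101 probe sets with no missing values, and their medians lie between 5.93 and 6.00. Values were used as deposited, with no further scaling or filter. The median change of all genes was -0.04, 0.04 and -0.01 (log2) in the comparisons of knockout with control, rescue with knockout and rescue with control. All 36 pairs of arrays were checked for identical columns, and 0 were identical. Arrays have no read depth, and their number limits the precision: the median standard error of a log2 change was 0.147.

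Of the probe sets, 34958 carried 1 gene symbol in the 2016 platform annotation, 932 carried several and 9211 carried none. Of the 18194 Entrez identifiers, 18032 matched a current gene name. Each of 18193 genes was represented by the probe set with the highest mean over the 9 arrays, among 34945 that carried its symbol alone and were not array controls. More than 1 probe set read 9010 of these genes.

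Genes were tested with limma 3.58.1 in R 4.3.3, and tables were read with version 1.17.8 of data.table. A model with 3 group means was fitted to all 9 arrays with lmFit and eBayes, so that the groups shared 1 estimate of spread. Tests were two-sided, and p-values were adjusted over all genes of a comparison by the method of Benjamini and Hochberg, with a threshold of 0.05. Changes are given on the log2 scale with limma's standard error from 3 arrays per group. Background flattens changes of dim genes, so a fold is given as at least its value where the lower of the 2 group means lay in the dimmest 40% of that group's genes. A gene was called separated where all arrays of either group lay above all arrays of the other.

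The comparisons, the tests, 35 gene lists and the rule for the genes named were set before the data were examined. The rule took Tfrc, the gene of Tfr1; Plagl2, Lgr5, Vim and Cdh1; the 10 largest rises and 10 largest falls among separated genes past the threshold; and up to 4 members with the smallest p from each list. Plagl2, Lgr5, Vim and Cdh1, and lists on iron, lipids, stem cells and epithelial-mesenchymal transition, were chosen from what is known of the study, so their results are not independent evidence for it. Further pathway lists covered HIF and glycolysis, mitochondrial respiration, haem synthesis, fatty acid oxidation, cholesterol synthesis, the cell cycle, junctions and keratins, and fetal and regenerative epithelium. Others covered the unfolded protein response, the integrated stress response, p53 targets with apoptosis, antioxidants, inflammation and interferon. Marker lists covered enterocytes, goblet, enteroendocrine, Paneth and tuft cells, fibroblasts, smooth muscle, endothelium, leukocytes, erythroid cells, neurons and glia, mesothelium, pancreas, 3 gut regions and sex-specific transcripts. Of the 726 symbols listed, 661 were measured.

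Lists were tested with limma's camera, which compares the members with all other genes, with a preset correlation between genes of 0.01 and adjustment over the 35 lists. Camera was run again with a correlation estimated from the arrays, and fry was run as a test of whether members moved, on balance, in the same direction. Members past the gene test were counted with p-values adjusted over all genes and adjusted over the list alone.

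The comparisons share arrays, so chance alone makes their changes correlate. That effect was simulated 20 times with no difference between groups and with the same spread of a gene in every group. The position of rescue between control and knockout was compared with 20 simulations each of no difference, of rescue at the control mean and of rescue at the knockout mean, chosen after the data were seen. The gene and list tests were also tested on simulated data with 50 changed genes at each size. In the simulated comparison of knockout with control, 10 of 50 genes were found at a log2 change of 0.5, 28 at 1, 47 at 1.5 and 47 at 2, with 5 false calls among 18193 genes. The corresponding numbers were 11, 32, 47 and 45 with 8 false calls for rescue with knockout, and 12, 31, 43 and 47 with 9 false calls for rescue with control. A simulated shift of 1 list was found in each comparison, and 1, 0 and 0 of the 34 other lists were called. Genes were drawn independently in these simulations. They therefore cannot show how list calls with the preset correlation hold where members correlate, as the fibroblast list did at an estimated 0.71.

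Alternatives left out each array in turn, averaged the probe sets of a gene, left out probe sets that may match several genes by their ending, left out the dimmest 40 percent of genes and tested each probe set on its own. Others changed the normalization, the prior, the array weights, the samples in the fit, the fold threshold and the list test. An alternative with replicate number as a block was also run. With group means removed, pairs of the same number across groups correlated at -0.22 to 0.40, and pairs of different numbers at -0.29 to 0.36. A further 4 alternatives were added after the data were seen: genes on X and Y left out, the mean of the fibroblast list as a covariate, the mean of the spike-in probe sets as a covariate, and knockout replicate 3 as the sole knockout array.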

Results

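Transcript levels were compared between intestinal epithelial cells of control, knockout and rescue pups on postnatal day 0, with 3 arrays per genotype. Tfr1, encoded by Tfrc, is the receptor that takes transferrin-bound iron into cells. The knockout removes it from intestinal epithelium, and the rescue adds a Tfr1 with the R654A change, which strongly weakens transferrin binding. Within groups, arrays correlated with r between 0.994 and 0.996 for control, 0.951 and 0.985 for knockout and 0.987 and 0.990 for rescue, across genes, which are not independent replicates. The median standard deviation of a gene was 0.104 in control, 0.225 in knockout and 0.140 in rescue (log2, n = 3 each).

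The targeted gene was read by 6 probe sets that gave different pictures. The brightest, which represented Tfrc in the gene test, read 10.21, 10.78 and 9.88 in the control arrays. It read 10.76, 11.16 and 9.07 in the arrays labelled knockout, and 10.91, 10.22 and 11.11 in the rescue arrays. Its change between knockout and control was 0.04 ± 0.51 (adjusted p = 0.97), that between rescue and knockout 0.42 ± 0.51 (adjusted p = 0.72), and that between rescue and control 0.46 ± 0.51 (adjusted p = 1.0). Another 2 probe sets with the gene's symbol read 6.15 and 4.67 in control, 5.88 and 4.31 in knockout, and 10.85 and 8.83 in rescue. Their control levels lay in the dimmest 40% of genes, so the rises over control were at least 26.0-fold and at least 18.0-fold. Averaging the probe sets that carry the gene symbol therefore called Tfrc higher in rescue than in knockout, by 3.31 (adjusted p = 7.8e-04). The signal of 5 of the 6 probe sets thus marks every rescue array with added receptor transcript. Between knockout and control the change of these 5 was -0.23 to -0.36, and none passed limma's test over all probe sets (adjusted p = 0.14 to 0.33). The parts of the transcript that the probe sets read, and the deleted exons, were not analysed here, so the values check neither the deletion nor the R654A change.

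**Figure D1:**
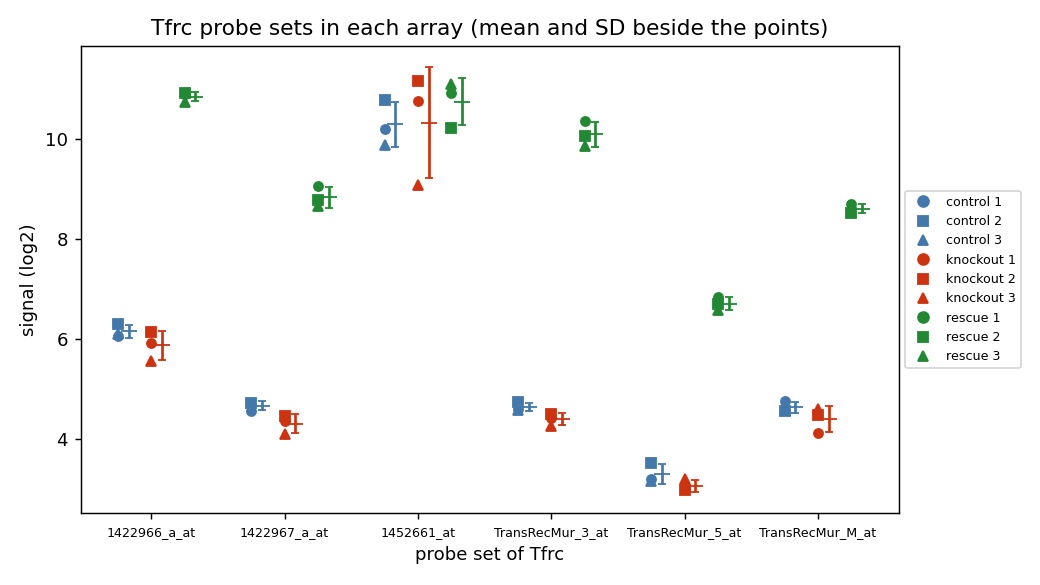
Log2 signal of the 6 Tfrc probe sets, 3 of them array controls, in each of the 9 arrays, with the mean and standard deviation of each group beside its points (n = 3). In the brightest probe set the 3 groups overlap, while in the others the rescue arrays lie above all control and knockout arrays.

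Knockout arrays lay apart from the rest and from each other. The first principal component held 56.1% of the variance and placed control arrays between -38.8 and -31.1, rescue arrays between -15.6 and -0.59, and knockout arrays between 7.02 for replicate 3 and 73.1 for replicate 1. Knockout replicate 3 stood alone on the second component, with 17.9% of the variance, at -55.2. Markers of fibroblasts, smooth muscle, and neurons and glia put the knockout arrays in the order of the first component, while those of mesothelium and pancreas were highest in replicate 2. The median fibroblast marker lay 3.92, 3.03 and 0.30 above the control mean in knockout replicates 1, 2 and 3, and between 0.31 and 0.62 above it in rescue arrays. The cell cycle list lay 0.76 and 0.77 above control in knockout replicates 1 and 2, and 0.39 below it (-0.39) in replicate 3.

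**Figure D2:**
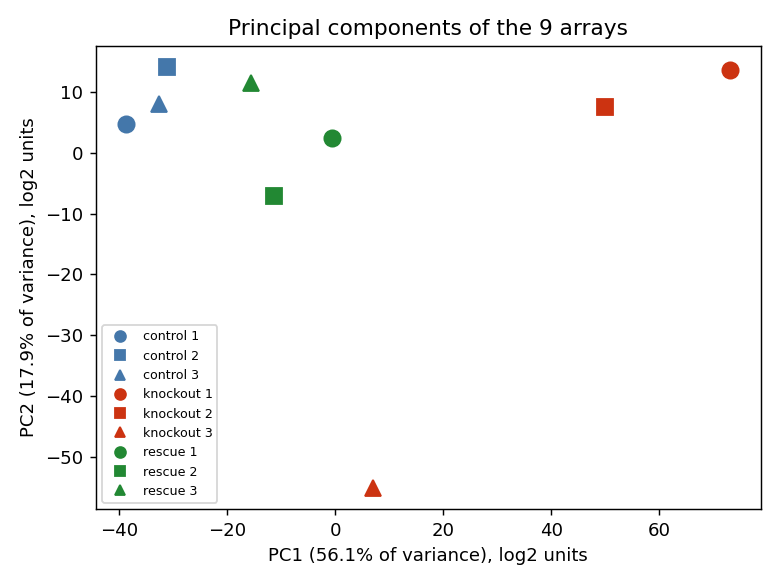
Principal components 1 and 2 of the 9 arrays (log2 units; share of variance on the axes), with colour for group and shape for replicate. Knockout replicates 1 and 2 lie at the right and replicate 3 at the bottom, at -55.2 on component 2.

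The comparison of knockout with control asks which transcripts change when intestinal epithelium lacks Tfr1. Knockout cells had far higher levels of Anxa10, an annexin, which rose by 5.85 ± 0.52 (at least 57.7-fold, adjusted p = 6.9e-04), and of Ada, the enzyme that breaks down adenosine, at 25.8-fold. Nrk, a kinase, rose at least 20.5-fold, and Plat, the tissue plasminogen activator, at least 19.7-fold. Sapcd2, a regulator of spindle orientation, fell by 3.81 ± 0.31 (14.0-fold, adjusted p = 4.6e-04), the kinesin Kif12 fell at least 13.6-fold and Fbp1, an enzyme of gluconeogenesis, 11.2-fold. Plagl2, a transcription factor, fell by 1.40 ± 0.17 (adjusted p = 0.0021) and read 8.95 to 9.52 in knockout arrays against 10.6 to 10.8 in control. The stem cell receptor Lgr5 (0.40 ± 0.43, adjusted p = 0.60) and the mesenchymal filament gene Vim (3.00 ± 0.95, adjusted p = 0.071) did not pass, and Vim read 11.7, 11.4 and 7.64 in knockout replicates 1, 2 and 3.

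In all, 2559 of 18193 genes passed between knockout and control, 963 higher and 1596 lower, and 949 of them changed at least 2-fold, 510 higher and 439 lower. Of these calls, 2554 were separated. Over all genes, 32.4% were separated, where chance gives 10% for 3 arrays against 3. The count was 1102, 1212 and 936 without control replicates 1, 2 and 3, 1629 without knockout replicate 1 and 4998 without knockout replicate 3. With the fibroblast mean as a covariate 1866 genes passed, 957 of them among the 2559, and with knockout replicate 3 as the sole knockout array 2560 passed, 1331 of them shared. Of the 20 genes with the largest changes, 18 stayed past the threshold in each of the 9 fits without 1 array, all but Slc5a12 and St6galnac1.

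Genes of fetal and regenerative epithelium rose together: 11 of 14 were higher and 0 lower, and 12 when adjusted over the list alone (camera adjusted p = 2.5e-10). Anxa1 rose 7.82-fold, Clu 6.53-fold, Anxa3 at least 6.33-fold and Krt23, a keratin, 3.25-fold. The list of p53 targets and apoptosis genes, the p53 list below, rose as well, with 10 of 22 higher and 0 lower (camera adjusted p = 1.8e-08). Adjusted over the list alone, 10 were higher and 1 lower. Among them the cell cycle inhibitor Cdkn1a rose by 2.35 ± 0.23 (5.10-fold, adjusted p = 9.4e-04), Phlda3 6.02-fold, Plk2 4.29-fold and Mdm2, which targets p53 for degradation, 2.15-fold. Of 22 enteroendocrine genes 9 were higher and 0 lower, and 14 adjusted over the list alone (camera adjusted p = 1.5e-08). The hormone genes Ghrl, Sst and Gip rose 3.23-fold, 2.32-fold and 1.80-fold. With an estimated correlation these were the 3 of 23 lists still called, at adjusted p = 0.041, 0.041 and 0.020. Their medians were above control in every knockout array. In replicates 1, 2 and 3 the fetal list lay at 2.05, 1.88 and 1.5 and the p53 list at 0.68, 0.56 and 0.48. Enteroendocrine genes lay at 0.85, 0.84 and 0.74.

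More junction and keratin genes rose than fell in knockout cells, with 13 of 29 higher and 0 lower, and 14 higher and 1 lower adjusted over the list alone. The test gave a camera adjusted p = 7.8e-07, and adjusted p = 0.28 with an estimated correlation. The tight junction gene Cldn3 rose 3.14-fold, Krt20, a keratin of mature enterocytes, 4.41-fold and the desmosomal cadherin Dsg2 1.93-fold. Cdh1, the epithelial cadherin, rose 1.27-fold (0.34 ± 0.10, adjusted p = 0.049), but missed the threshold in 8 of the 9 fits without 1 array, with an adjusted p of up to 0.15.

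Of 26 genes of epithelial-mesenchymal transition 5 were higher and 0 lower, and 20 higher adjusted over the list alone (camera adjusted p = 1.3e-09; adjusted p = 0.21 with an estimated correlation). Fn1, which encodes fibronectin, rose by 3.78 ± 0.23 (13.8-fold, adjusted p = 1.8e-04) and read 10.7, 10.9 and 11.6 in knockout replicates 1, 2 and 3, against 7.01 to 7.56 in control. The membrane protease Mmp14 rose 2.67-fold and the matrix gene Tgfbi 3.45-fold. The median of the list lay 2.00, 1.70 and 0.30 above control in knockout replicates 1, 2 and 3.

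Markers of cells of the intestinal wall moved in the same arrays. Of 21 fibroblast genes 3 were higher, and 18 adjusted over the list alone (camera adjusted p = 1.5e-08; adjusted p = 0.37 with an estimated correlation), among them Pdgfra (3.86-fold), Col6a1 and Col6a2. Pdgfra missed the threshold in 4 of the 9 fits without 1 array and the other two in 8 each (adjusted p up to 0.14). Smooth muscle (1 of 14 higher, 8 over the list alone, adjusted p = 0.39 with an estimated correlation) and endothelium (3 of 17, 7 over the list alone, adjusted p = 0.37 so estimated) were called with the preset correlation, at 1.8e-04 and 8.6e-06. So were neurons and glia (3 of 14 higher, 2.0e-04, and adjusted p = 0.29 with an estimated correlation) and mesothelium (3 of 8 higher, 0.0013, and adjusted p = 0.30 likewise). The neuron and glia median was 2.42, 1.40 and 0.16, and the smooth muscle median 1.98, 0.96 and 0.13, in knockout replicates 1, 2 and 3. With the fibroblast covariate the smooth muscle list turned downward, with no call (0.848). Of 20 leukocyte genes 4 were higher and 2 lower, and 10 higher and 2 lower adjusted over the list alone (camera adjusted p = 1.4e-04, and adjusted p = 0.21 with an estimated correlation). The neutrophil gene S100a8 rose at least 5.03-fold, and Lcp1, an actin-bundling gene, fell 2.70-fold.

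**Figure D3:**
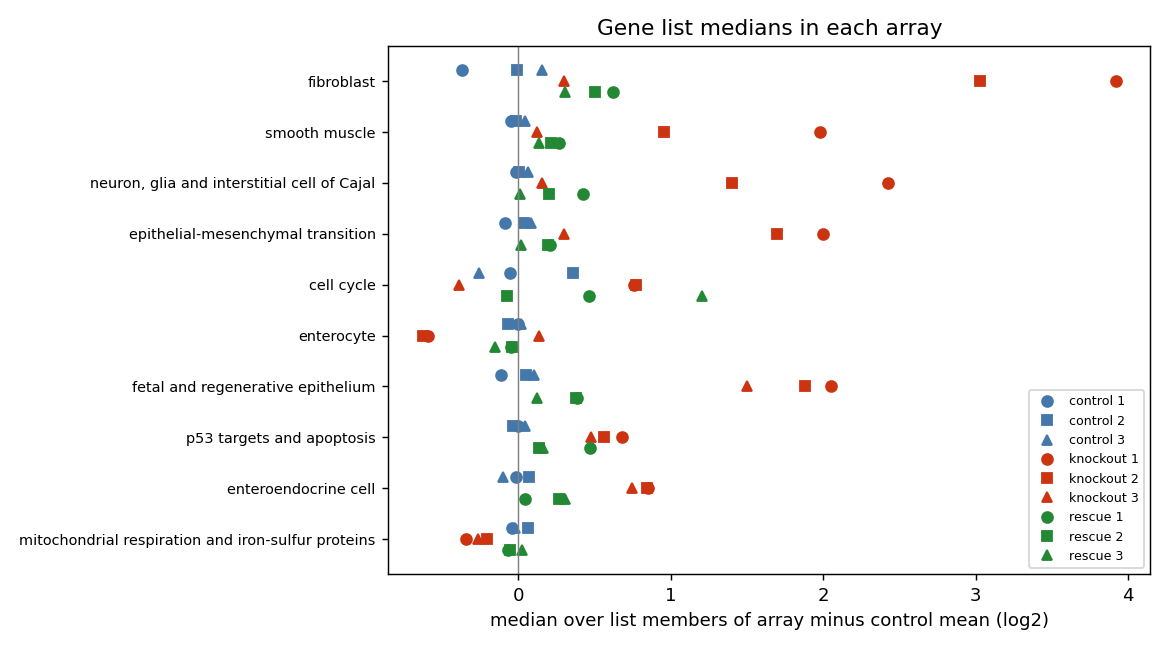
Median over the members of 10 gene lists of each array's value minus the control mean (log2), with colour for group and shape for replicate. Fibroblast, smooth muscle, neuron and transition genes are high in knockout replicates 1 and 2 and near control in replicate 3, while the fetal, p53 and enteroendocrine lists are above 0 in all 3 knockout arrays.

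Some genes of mitochondrial respiration and haem synthesis were lower in knockout cells by small amounts, with list calls that an estimated correlation did not keep. Of 28 genes of mitochondrial respiration and iron-sulfur proteins 8 fell and 0 rose, and 14 fell adjusted over the list alone (camera adjusted p = 4.5e-04; adjusted p = 0.40 with an estimated correlation). Ndufs8, an iron-sulfur subunit of complex I, fell by 0.65 ± 0.11 (1.57-fold, adjusted p = 0.0079). Haem synthesis had 5 of 11 lower, 7 over the list alone (camera adjusted p = 0.0012; adjusted p = 0.39 with an estimated correlation), among them the transporter Abcb6 (1.60-fold). In the iron list 2 of 25 genes rose and 1 fell, with no shift of the list (camera adjusted p = 0.74). Ltf, the iron-binding lactoferrin, rose 2.69-fold. Targets of HIF and glycolysis had 6 of 27 higher and 0 lower, and 7 over the list alone (camera adjusted p = 0.0018; adjusted p = 0.28 with an estimated correlation). The hexokinases Hk1 and Hk2 rose 5.65-fold and 4.16-fold.

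Lipid genes moved in both directions. Of 24 genes of fatty acid oxidation and PPAR targets 7 fell and 2 rose, and 13 fell and 3 rose adjusted over the list alone. The list's call (camera adjusted p = 0.013, and adjusted p = 0.51 with an estimated correlation) was lost without knockout replicate 1 (adjusted p = 0.057). Its median was -0.84, -0.43 and -0.24 in knockout replicates 1, 2 and 3. With the fibroblast mean as a covariate 3 of the 24 genes were higher and 0 lower, and the median change was -0.21, against -0.49 without it. Eci1 and Acads, enzymes of oxidation, fell 2.41-fold and 1.71-fold, while Angptl4, a secreted inhibitor of lipoprotein lipase, rose by 3.66 ± 0.46 (12.6-fold, adjusted p = 0.0024) and Pdk4, which restrains pyruvate oxidation, 10.7-fold. Synthesis of cholesterol and fatty acids had 6 of 26 lower and 0 higher, and 7 over the list alone (camera adjusted p = 0.0016; adjusted p = 0.21 with an estimated correlation), with Mvd, Nsdhl and Dhcr7 at 1.80-fold, 1.86-fold and 1.86-fold lower. Lipid uptake and chylomicron assembly had 2 of 28 lower, 0 adjusted over the list alone, and a direction that hung on the arrays (camera adjusted p = 0.74). The list was called downward without knockout replicate 3 (adjusted p = 0.044), and upward with knockout replicate 3 as the sole knockout array (0.021) or with the fibroblast covariate (0.00522).

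Stress and immune genes gave mixed results. The unfolded protein response had 5 of 22 lower and 0 higher, and 6 lower and 1 higher over the list alone (camera adjusted p = 0.0055; adjusted p = 0.45 with an estimated correlation), with the chaperone genes Sdf2l1 and Pdia4 down 1.66-fold and 1.51-fold. The integrated stress response had 4 of 22 higher and 1 lower (camera adjusted p = 0.090), and the lipoprotein receptor gene Vldlr rose 7.15-fold. Antioxidant genes had 2 of 22 higher and 4 lower (camera adjusted p = 0.74), with catalase (Cat) 2.09-fold lower. Inflammatory genes had 6 of 26 higher and 2 lower (camera adjusted p = 0.0011; adjusted p = 0.21 with an estimated correlation): the chemokine gene Cxcl2 rose at least 2.35-fold and the cytokine gene Il18 fell 3.26-fold. Of 20 interferon genes 1 was higher and 1 lower (camera adjusted p = 0.29).

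Among epithelial cell types, 4 of 27 enterocyte genes fell and 0 rose, and 5 fell adjusted over the list alone. The regulator Cdx1 fell 2.92-fold and Lct, the gene of lactase, 1.86-fold. The enterocyte median was -0.59, -0.63 and 0.14 in knockout replicates 1, 2 and 3, and the list's call (camera adjusted p = 0.030; adjusted p = 0.60 with an estimated correlation) was lost without replicate 1 (0.27) or 2 (0.097). The direction turned upward, with no call, with the fibroblast covariate (0.134) and with replicate 3 alone (0.318). Of 21 goblet genes 3 rose and 1 fell (camera adjusted p = 0.0050; adjusted p = 0.42 with an estimated correlation), among them the lectin gene Zg16, which rose 12.5-fold. Paneth and antimicrobial genes had 4 of 13 higher (camera adjusted p = 0.034; adjusted p = 0.23 with an estimated correlation), a call lost without knockout replicate 3 (0.14) or rescue replicate 1 (0.053). The lysozyme gene Lyz1 rose 21.3-fold by a probe set whose ending marks possible matches to other genes, and by 0.70 with an adjusted p of 0.062 when such probe sets were left out. The tuft list had 1 of 11 higher (camera adjusted p = 0.22).

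Stem cell and Wnt targets had 2 of 26 higher and 2 lower: Cdk6 rose 2.49-fold, and the lower genes were Plagl2 and Aqp4, the latter lost in 4 of the 9 fits without 1 array (adjusted p up to 0.073). The list was called upward (camera adjusted p = 0.030; adjusted p = 0.49 with an estimated correlation), but not without control replicate 1 (0.081) or 3 (0.055) or knockout replicate 1 (0.10) or 2 (0.15), and it turned downward, with no call, with the fibroblast covariate (0.852) and with knockout replicate 3 alone (0.922). Of 29 cell cycle genes 0 passed in limma's test, and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.055), and the list was called upward without control replicate 2 (0.0067), knockout replicate 3 (7.3e-04), rescue replicate 2 (0.031) or rescue replicate 3 (0.035). The ileum list had 3 of 8 higher (camera adjusted p = 0.13), with the bile acid genes Fabp6 and Slc10a2 up 13.3-fold and at least 5.27-fold. Colon (1 of 12 higher and 1 lower, camera adjusted p = 0.25), proximal small intestine (0 of 10 in limma's test, 3 at an unadjusted p under 0.05, camera 0.56), erythroid (1 of 14 higher, 0.22) and sex-specific lists (0 of 5, 1 unadjusted, 0.79) showed no shift past the threshold. Pancreas genes had 0 of 10 past limma's gene test and 1 unadjusted (camera adjusted p = 0.012; adjusted p = 0.49 with an estimated correlation), with medians of 0.18, 2.33 and 0.51 in knockout replicates 1, 2 and 3 and no call without replicate 2 (0.19).

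The comparison of rescue with knockout asks how the R654A receptor moves transcripts of cells that lack the normal one. Several of the largest knockout changes moved back toward control. Angptl4 fell by 3.94 ± 0.46 (15.3-fold, adjusted p = 0.0071), Plat at least 12.3-fold, Fn1 9.29-fold and Nrk 8.33-fold, while Sapcd2 rose by 2.63 ± 0.31 (6.21-fold, adjusted p = 0.0071) and Kif12 at least 5.22-fold. Acvr1c, a receptor of the activin family, rose at least 4.05-fold. The largest changes of all were sex-specific: Xist, expressed from the inactive X, read 12.2 in control, 12.5 in knockout and 6.67 in rescue arrays, and the Y-linked Eif2s3y read 2.78, 2.63 and 9.51. Sex therefore differed between the rescue arrays and the rest.

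Between rescue and knockout 420 genes passed, 224 higher and 196 lower, and 209 changed at least 2-fold, 81 higher and 128 lower. All 420 were separated, and over all genes 18.1% were separated against 10% by chance. Of the 420, 14 lie on X or Y. The count fell to 175, 171 and 152 without control replicates 1, 2 and 3, to 204 and 226 without knockout replicates 1 and 2, and to 192, 135 and 105 without rescue replicates 1, 2 and 3. It was 2793 without knockout replicate 3, and that set held all 420. With the 6 arrays of the compared groups alone it was 30, with the fibroblast mean as a covariate 857, and with knockout replicate 3 as the sole knockout array 1096.

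The 3 lists whose rise in the knockout held with an estimated correlation fell in the rescue by the same test. Both comparisons use the same knockout arrays, so this fall is not independent of the rise. Between rescue and control none of the 3 was called with an estimated correlation (camera adjusted p = 0.10, 0.053 and 0.053 for the fetal, p53 and enteroendocrine lists). With the preset correlation all 3 were called upward there (camera adjusted p = 2.5e-05, 1.7e-06 and 2.3e-04), at median changes of 0.38, 0.29 and 0.25. A full return to the control level is therefore not shown. Of 14 fetal and regenerative genes 5 fell, 10 adjusted over the list alone (camera adjusted p = 9.8e-11; adjusted p = 0.041 with an estimated correlation), with Clu 4.65-fold and Anxa1 4.22-fold lower. Of the 22 genes of the p53 list 6 fell and 0 rose, and 9 fell and 1 rose adjusted over the list alone (camera adjusted p = 2.1e-07, and adjusted p = 0.041 with an estimated correlation). Cdkn1a fell by 1.30 ± 0.23 (2.46-fold, adjusted p = 0.030) but missed the threshold in 5 of the 9 fits without 1 array (adjusted p up to 0.10). Of 22 enteroendocrine genes 2 fell, 8 adjusted over the list alone (camera adjusted p = 7.8e-08; adjusted p = 0.026 with an estimated correlation), with Ghrl 2.06-fold lower and past the threshold in all but 5 of those fits (adjusted p up to 0.11). The other 16 of the 19 lists called with the preset correlation were not called with an estimated one.

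Transition genes were lower in rescue for 2 of 26, Fn1 and Mmp14 (2.73-fold), and 7 adjusted over the list alone (camera adjusted p = 8.6e-11; adjusted p = 0.18 with an estimated correlation). Fibroblast genes had 0 of 21 past limma's gene test, and 11 at an unadjusted p under 0.05, beside a list call (camera adjusted p = 5.6e-08; adjusted p = 0.44 with an estimated correlation) that turned upward, with no call, with knockout replicate 3 alone (0.610). Mitochondrial genes had 1 of 28 higher, 7 adjusted over the list alone (camera adjusted p = 3.2e-05; adjusted p = 0.44 with an estimated correlation). Among metabolic genes Pdk4 fell 5.44-fold, Ltf fell 4.09-fold and Elovl6, a fatty acid elongase, rose 1.82-fold. Plagl2 rose by 1.01 ± 0.17 (2.01-fold, adjusted p = 0.026) and missed the threshold in 7 of the 9 fits without 1 array (adjusted p up to 0.10). Vim (-1.89 ± 0.95, adjusted p = 0.32), Cdh1 (-0.20 ± 0.10, adjusted p = 0.31) and Lgr5 (0.04 ± 0.43, adjusted p = 0.97) did not pass.

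The comparison of rescue with control asks what stays different when the R654A receptor is present. Rescue arrays also differed in sex from control arrays, so effects of genotype and of sex cannot be told apart in it. Zg16, a lectin of goblet cells, was higher by 2.82 ± 0.32 (7.05-fold, adjusted p = 0.035) and Clca1, another secreted goblet product, 2.94-fold. Phlda1 was 2.65-fold and Vldlr 2.64-fold higher. Fermt3, an integrin activator of blood cells, was 4.19-fold, C1qtnf12 4.15-fold and the DNA methyltransferase gene Dnmt3b 2.09-fold lower. Of 21 goblet genes 2 were higher and 0 lower, and 6 adjusted over the list alone (camera adjusted p = 3.9e-14; adjusted p = 0.092 with an estimated correlation). The goblet median was 0.10, 0.72 and 0.84 above control in rescue replicates 1, 2 and 3.

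Between rescue and control 23 genes passed, 10 higher and 13 lower, against 1205 at an unadjusted p under 0.05. All 23 were separated, and over all genes 16.6% were separated, where chance gives 10%. Of the 23, 4 lie on X or Y, and with the genes of X and Y left out 10 passed in all. Clca1 (adjusted p = 0.0527), Vldlr (0.0572) and Dnmt3b (0.0524) were among those no longer past the threshold. The count was 3, 2 and 2 without control replicates 1, 2 and 3, 11 and 136 without knockout replicates 2 and 3, and 10 and 2 without rescue replicates 1 and 2. Of the 20 genes with the largest changes only Eif2s3y and Xist passed in every fit without 1 array. Of 35 lists 14 were called by camera with the preset correlation, 0 with an estimated one and 6 by fry. Plagl2 (-0.39 ± 0.17, adjusted p = 0.73), Vim (1.10 ± 0.95, adjusted p = 1.0), Cdh1 (0.15 ± 0.10, adjusted p = 0.98) and Lgr5 (0.44 ± 0.43, adjusted p = 1.0) did not pass.

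Of the genes called between knockout and control, 405 were also called between rescue and knockout in the opposite direction, 187 that were higher in the knockout and 218 that were lower. Independent calls would give 10.4 and 19.7, and simulations with no group difference gave 0. The changes correlated at r = -0.90 across genes with a covariance of -0.234, beside -0.50 and -0.0294 in these simulations. The simulations drew genes independently and gave a gene the same spread in every group. The median standard deviation was in fact 0.225 in knockout, 0.104 in control and 0.140 in rescue. The simulated values therefore understate what the shared knockout arrays alone would give, and the gap to the measured values is not a measure of reversal. The rescue mean lay between control and knockout for 2407 of the 2559 genes (94.1%), past control for 4.69% and past knockout for 1.25%, with a median of 34.5% of the change left. The same arrays chose the genes and set the interval, which alone places many rescue means inside it: over as many genes, simulations gave 67.7% with no group difference, 61.4% with rescue drawn at the control mean and 61.5% with rescue drawn at the knockout mean. The median share left was 49.9%, 5.46% and 94.6% in these simulations. The opposite overlap was 167, 164 and 147 without control replicates 1, 2 and 3, 197, 221 and 2620 without knockout replicates 1, 2 and 3, and 184, 128 and 99 without rescue replicates 1, 2 and 3. A further 20 genes were called in the same direction against control in both knockout and rescue, 8 higher and 12 lower. Independent calls would give 0.53 and 1.14 and simulations with no group difference 0. Without a group difference hardly any gene passes, so a simulated overlap of 0 was near certain in both pairs of comparisons. Independent calls take no account of the shared control arrays. Neither value measures how much of the knockout change stays in the rescue. For the shared control arrays, the simulations with no group difference gave a correlation of 0.50 and a covariance of 0.0292, beside the measured 0.73 and 0.124. That overlap of 20 was 1, 0 and 0 without control replicates 1, 2 and 3, 9 and 127 without knockout replicates 2 and 3, 7 and 0 without rescue replicates 1 and 2, and 14 without knockout replicate 1 or rescue replicate 3.

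**Figure D4:**
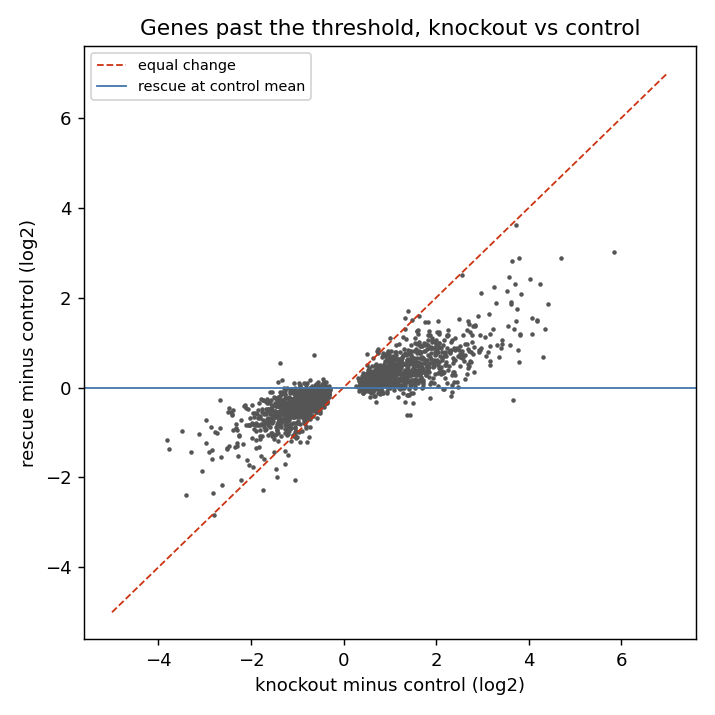
Rescue minus control against knockout minus control (log2) for the 2559 genes past the threshold between knockout and control, 1 point per gene. Most points lie between the solid line at the control mean and the dashed line of equal change, with 94.1% of the rescue means between control and knockout, against 67.7% in simulations with no group difference; both axes share the control arrays.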

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

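The tests of wall cells, of a loss of junction and keratin genes and of enterocyte genes, of a wrong group label, of spike-in levels and of sex, and the alternatives with a fibroblast covariate and with X and Y left out, were chosen after the result was seen. Array control probe sets for the mouse transferrin receptor, which no comparison used, gave a signal in rescue arrays above that in control arrays, which lay near background. The probe set at the 3′ end read 4.63 in control and was at least 44.0-fold higher in rescue, that at the 5′ end read 3.30 and was at least 10.6-fold higher, and that in the middle read 4.63 and was at least 15.7-fold higher. Of 9160 probe sets with no gene listed and outside the array controls, 336 passed between knockout and control, 174 of them higher in the knockout. Between rescue and knockout 46 of them passed, and between rescue and control 8.

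Among the 3 groups 1431 genes passed limma's F test. Of 100 splits of the 9 arrays into 3 groups of 3, the real one included, 1 gave as many genes, and the highest other count was 200. A chance split is thus unlikely to give this count, though 1 in 100 is the smallest share these splits can give. The splits treat arrays as interchangeable, which the labels do not settle. The real groups also differ in sex and in wall-cell markers, and the splits cannot tell these from genotype. The 1431 genes were 536, 617 and 426 without control replicates 1, 2 and 3, and 796, 893 and 3723 without knockout replicates 1, 2 and 3. For 2 groups of 3 arrays the 10 splits are too few for a share under 0.05. The real split alone (1 of 10 in each comparison) gave 2559, 420 and 23 genes for knockout with control, rescue with knockout and rescue with control, and the highest other counts were 0, 1 and 0.

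Some mesenchymal genes were higher in knockout arrays beside abundant fibroblast transcripts such as Col3a1 (9.02 in control, 11.9 in knockout) and Col1a2 (8.36 and 11.2), and the preparation named no sort that would remove such cells. With the mean of the fibroblast list as a covariate the median change of the transition list dropped from 1.49 to 0.10. The lists share 0 genes, and 9 of 21 fibroblast genes lay above the median gene in control. Cells of the intestinal wall may account for much of the list. The drop cannot tell this from a gain of mesenchymal genes in epithelial cells, since fibroblast genes could rise with either. Of the 5 members past the threshold 3 still passed: Fn1 (3.78 ± 0.23 before, 4.28 ± 0.26 after), Mmp14 (1.42 ± 0.10 and 1.32 ± 0.15) and, near the threshold, Tgfb1 (0.34 ± 0.09 and 0.48 ± 0.12, adjusted p = 0.046). This cannot decide whether wall cells are the whole cause for these genes. A gene passed without the covariate more readily if also high in knockout replicate 3, whose fibroblast list mean of 6.84 was near control (6.19 to 6.78). Without that array 20 of 26 members passed. Fn1 and Mmp14 read 11.6 and 8.27 in replicate 3, against 7.01 to 7.56 and 6.88 to 6.91 in control. The calls of Tgfbi (1.79 ± 0.36 before, 1.12 ± 0.45 after, adjusted p = 0.16) and Itgav (0.83 ± 0.18 and 1.0 ± 0.27, adjusted p = 0.051) ended, the first with a smaller change and both with a wider error. A gain of mesenchymal genes with a loss of junction and keratin genes in the same cells is argued against by 13 of these genes that were higher and 0 that were lower, although that list was not called with an estimated correlation (adjusted p = 0.28); a gain with a loss of enterocyte genes stays open, since 4 of 27 were lower and 0 higher but the list was not called so either (0.60), as does a change in a small share of cells.

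Knockout replicate 3 lay apart from replicates 1 and 2, with which it correlated at 0.951 and 0.966. Its correlations were higher with every control array (0.967 to 0.970) and with every rescue array (0.971 to 0.981). Of the 4998 genes called without it, 81.5% lay on the knockout side of control in it, at a median of 0.404 of the size in the other knockout arrays, which argues against a control array under a wrong label; its receptor control probe set read 4.27 at the 3′ end, against 9.86 to 10.4 in rescue arrays, which argues against a rescue array. Spike-in levels are argued against as well: control replicate 1, with a mean of 9.49 beside 9.51 in knockout replicate 3, correlated at 0.994 or more with the other control arrays, above the highest value between control and knockout arrays (0.970). The cell cycle median of replicate 3 lay below those of replicates 1 and 2 by a difference of -1.15 at the least, so fewer dividing cells in that preparation may be a part of the difference. Rescue replicates 2 and 3, however, had cell cycle medians of -0.07 and 1.21 and still correlated at 0.990. A gap in this median need not set arrays apart, so it cannot decide the question. Wall-cell markers differed between the knockout arrays as well, with a fibroblast list mean of 6.84 in replicate 3 beside 9.94 and 9.28 in replicates 1 and 2. How much of the difference the share of wall cells accounts for was not tested. A different stage of the pups stays open and untested.

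Rescue arrays differed from knockout arrays in sex-specific transcripts as well as in genotype. If sex were the whole cause, genes outside X and Y would differ from control as they do from knockout, since control and knockout arrays gave the same sex. Over 406 such genes the slope of rescue minus control on rescue minus knockout was -0.28, and 83.0% went the opposite way, which argues against sex as the whole cause. Genotype is the difference the design names and remains a hypothesis. What sex adds to a single gene stays open, since the rescue arrays hold only the sex that the others lack.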

How the results depend on the processing

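Results with the fibroblast mean or the spike-in mean as a covariate, with X and Y left out and with knockout replicate 3 as the sole knockout array come from alternatives chosen after the data were seen. Over the alternatives set beforehand, named genes gave 4179 values, of which 3471 kept direction and side of the threshold, 663 no longer passed, 45 passed newly and 0 turned. List tests gave 2085 values, of which 1882 kept both, 131 lost and 70 gained a call and 2 turned, with turns counted only where either value passed; 44 more changed sign without a call. The added alternatives gave 926 gene values (795 kept, 123 lost, 8 newly passing, 0 turned) and 417 list values (338 kept, 46 lost, 15 gained, 18 turned). The array number limits what small changes can pass, and genes near background, such as most Tfrc probe sets in control arrays, can show only a small fall. Causes were not tested except where fewer arrays or genes are the alternative itself.

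Leaving out 1 array each gave 936 to 4998 genes for knockout with control, 105 to 2793 for rescue with knockout, 2 to 136 for rescue with control and 426 to 3723 among the 3 groups. The opposite overlap ranged from 99 to 2620 and the same-direction overlap from 0 to 127. The interferon list between rescue and knockout ranged in adjusted p from 0.0278 without knockout replicate 1, where it turned upward, to 0.972.

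With replicate number as a block the counts were 257 for rescue with knockout, 12 for rescue with control, 251 for the opposite and 9 for the same-direction overlap. Averaging probe sets gave a Tfrc change of 3.31 for rescue with knockout and 3.11 for rescue with control, since the other probe sets rise in rescue arrays. Repeated quantile normalization gave 15 genes for rescue with control and 12 in the same-direction overlap, and a trended robust prior 14 and 11. Array weights (0.166 for knockout replicate 3) gave 6395, 2453, 355 and 5522 genes for knockout with control, rescue with knockout, rescue with control and the 3 groups, overlaps of 2371 and 328, and a cell cycle list called in the other direction between rescue and knockout (adjusted p = 0.0302). The compared arrays alone gave 1655, 30 and 149 genes. An estimated correlation left 3, 3 and 0 lists and fry 15, 8 and 6. A 2-fold minimum left 949 and 209 genes for knockout with control and rescue with knockout. Testing each probe set gave 3942 for knockout with control, 63 for rescue with control and 2185 among the 3 groups. X and Y left out gave 10 genes for rescue with control and an overlap of 10.

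With the fibroblast covariate 857 genes passed for rescue with knockout and 112 for rescue with control, the overlaps were 781 and 98, and 7 and 12 lists were called for knockout with control and rescue with knockout. List directions turned for lipid uptake (adjusted p = 0.00522), stem cell and Wnt targets (0.852), enterocytes (0.134) and smooth muscle (0.848) in knockout with control. They turned for lipid uptake (0.0036), stem cell and Wnt targets (0.886), interferon (0.0173), enterocytes (0.149) and smooth muscle (0.762) in rescue with knockout, and for fibroblasts (0.980) in rescue with control. With knockout replicate 3 alone, assumed to vary like the other groups, 1096 and 149 genes passed for rescue with knockout and rescue with control, the overlaps were 1012 and 130, and 12 and 10 lists were called for knockout with control and rescue with knockout. Directions turned for lipid uptake (0.021), stem cell and Wnt targets (0.922) and enterocytes (0.318) in knockout with control. In rescue with knockout they turned for lipid uptake (0.00130), stem cell and Wnt targets (0.652), enterocytes (0.076), fibroblasts (0.610) and smooth muscle (0.204). The fetal, p53 and enteroendocrine lists were called in knockout with control and rescue with knockout under each alternative. The adjusted p was at most 0.041. The estimated correlation was an alternative of its own. It was not combined with left-out arrays, covariates or another normalization for these lists. How the calls with an estimated correlation depend on single arrays or on the fibroblast covariate was therefore not tested.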

Other observations

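The lists in this part, and the genes named in it, were chosen after single genes such as Dusp1, Lipf, Psca, Peg3, Lct, Fcgrt and Nox4 had been seen, and the expected outcomes were written before the values of the list members were seen. Some immediate early genes, which cells switch on within minutes of a stimulus, were higher in knockout arrays. Their list was called with the preset correlation (camera adjusted p = 7.0e-09), but not with an estimated one after adjustment. Dusp1, a phosphatase gene of this kind, rose by 2.70 ± 0.21 (adjusted p = 3.3e-04, n = 3 per group, above all control arrays in 3 of 3). Of 18 further genes 11 were higher, 0 were lower and the rest did not pass; the higher ones included Egr1 (6.69-fold), Klf6 (5.43-fold), Fos (4.91-fold) and Atf3 (2.44-fold). The median change was 0.70, so a rise of immediate early genes as a set may lie behind that of Dusp1. The camera test with an estimated correlation gave p = 0.027 and, over the 5 lists of this part, adjusted p = 0.13, and 3 of the 18 genes passed with the fibroblast mean as a covariate. A response to the isolation of the cells was not tested and stays open.

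Genes of the suckling-type enterocyte, which takes up milk proteins whole, were lower for 6 of 9 in knockout arrays. The uptake receptor genes Lrp2 and Amn fell 3.76-fold and 1.90-fold, Prdm1, a repressor that maintains this cell state, 3.30-fold, and Asl and Ass1 of arginine synthesis 3.14-fold and at least 2.25-fold. The median change was -0.97 with a spread over members of 1.01. The list was called with the preset correlation (camera adjusted p = 5.6e-05), while the camera p with an estimated correlation was 0.10. With the fibroblast mean as a covariate 1 of the 9 genes was lower and the median change was -0.59 (camera adjusted p = 0.023 with the preset correlation). A fall of the set behind those of Lct, Fcgrt and Nox4 could be neither shown nor excluded with these 9 genes.

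Lipf, the gastric lipase gene, rose at least 13.8-fold and Psca at least 2.32-fold in knockout arrays. Of 14 genes of gastric epithelium 2 were higher, Gkn1 (2.49-fold) and Tspan8 (1.92-fold), and the median was 0.17 with a spread of 0.471. The list was called with the preset correlation (camera adjusted p = 0.041) but not with an estimated one (camera p = 0.21), so a rise of the set stays open. Genes of parietal and chief cells had a median of 0.0375 with a spread of 0.0999, below the bound of 0.1 set beforehand against stomach tissue in the knockout preparations. That bound was wrong, since 5 of the 8 genes lay in the dimmest 40% in control, where a small share of such cells could stay hidden, so stomach tissue stays open; Pga5 of that list fell at least 3.28-fold. Tff2 ranged from 6.99 to 13.5 over the arrays without following the groups. Peg3, an imprinted growth gene, rose 6.31-fold (adjusted p = 4.9e-04). Of 13 imprinted genes Sgce (at least 3.02-fold) and Meg3 (2.92-fold) were higher and Cdkn1c (2.44-fold) was lower, and with the fibroblast mean as a covariate the median was 0.0106 with members on both sides, which decides nothing about a rise of the set.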
